A study of Mus musculus with 16 samples.

How the data were processed

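Total liver RNA of 16 mice was turned into SuperSAGE libraries. Per the labels, cDNA was made from a biotinylated oligo-dT primer, cut with NlaIII, captured on beads, cut with EcoP15I to release a tag, given index adapters and amplified by PCR. The deposited table holds raw tag counts per RefSeq transcript, in a column per mouse, per the file headers. How tags were matched, with which RefSeq release, and how tags found in several transcripts were treated are not given in the sources used here. The labels name no molecular identifiers, so PCR copies cannot be told from separate molecules, and limits based on counts cover counting error only. The labels also give no preparation or sequencing batch. No paired analysis was possible because no replicate number is shared between groups.

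The table has 26782 rows. Rows without a gene symbol (417, holding 0.0729% of all tags) were left out. For 41 symbols that had become dates, all but 1 were restored from the RefSeq identifier. Counts were summed per gene symbol, which gave 20826 symbols, 10171 of them with at least 1 tag. Library totals in named genes ran from 56655 to 149349 tags, with a median of 79475.5. Pairs of libraries of the same group were checked for duplicates, with a chi-square per degree of freedom of 2.24 to 9.64.

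Counts were analysed in R 4.3.3 with edgeR 4.0.16: trimmed mean of M-values normalization, the default expression filter by group (a minimum count of 10), which kept 1046 genes, and a robust quasi-likelihood fit of all 16 libraries with a mean per group. Tests were the quasi-likelihood F test with Benjamini-Hochberg adjustment at 0.05. Standard errors are the log2 fold change divided by the square root of F and are approximate. The contrasts were HF minus N, HFW minus HF, NW minus N, HFW minus NW, the interaction (HFW minus HF) minus (NW minus N), and the mean of both WEPAK contrasts. Group means are in CPM of the normalized library size, and log2 CPM used a prior count of 2.

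Gene lists (34), contrasts, tests and the rule for named genes were fixed before the data were examined. Of the lists 16 had the 5 tested members required for a test. They were tested with camera in limma 3.58.1 at a preset correlation of 0.01, as 1 family of 96 tests, of which 2 passed. With an estimated correlation 0 passed, and 0 with fry, which tests whether a list's genes move on balance in 1 direction.

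Named genes followed this rule: the 10 higher and 10 lower genes with the smallest p among those past the threshold in each contrast; where fewer than 5 passed, those plus up to 5 each way with the smallest unadjusted p; up to 4 members with the smallest p of each list; 14 genes of lipid and glucose metabolism and inflammation; and genes above 1% of a library. Some genes that meet the rule are not reported here.

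The same functions were tested on simulated counts with the mean abundance, library sizes and dispersions of the tested genes and 200 changed genes, in 5 simulations per contrast. In HFW minus HF, 11.9% of 1.5-fold, 44.8% of 2-fold and 90.0% of 4-fold changes were found, and 3.94% of calls were false. For the mean WEPAK effect 30.4%, 76.7% and 91.8% were found, with 4.47% false calls, and for HF minus N 10.7%, 43.3% and 92.7%, with 5.07%. Camera found 19 of 20 simulated lists of 11 genes shifted by -0.5 on the log2 scale and made 3 false calls among 300 unchanged lists. In all these simulations genes were drawn independently of each other. The rates therefore do not cover lists whose genes move together, and they do not test the preset correlation.

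Alternatives were DESeq2 size factors, no filter, a filter of at least 10 counts in each of 4 libraries, the DESeq2 1.42.0 Wald test, limma-voom, fits of the compared groups alone, a non-robust fit, RefSeq rows tested separately, and leaving out each mouse. The filter of at least 10 counts in each of 4 libraries was planned as a stricter one but kept 1220 genes, more than the 1046 of the default filter, so no stricter filter was tested. Chosen after seeing the data were thinning all libraries to the smallest total, removing per-library trends on GC content or on the number of NlaIII sites, leaving out the 10 most abundant genes, leaving out N mice 4 and 8, testing macrophage and stellate cell markers below the filter, prior counts of 0.5 and 5, and limiting the agreement of the WEPAK effects to abundant genes. Tag properties came from the last NlaIII site of GENCODE mouse transcripts, which may differ from the release behind the table, and a tag GC value was had for 94.4% of the tested genes.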

Results

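Liver transcripts of 16 male C57BL/6J mice were counted by SuperSAGE, a method that sequences a short tag beside an NlaIII site of each captured transcript. The mice fell into 4 feeding groups of 4. The N group ate a normal diet with 10% fat, the HF group a high-fat diet with 45% fat, and the NW and HFW groups the same diets with 1% WEPAK, a water-soluble extract of Pacific krill. Feeding lasted 18 weeks, and each library came from a separate mouse, named here by its group and number. Libraries held between 56684 and 149464 tags. The mean total in named genes was 118882 ± 23746 tags (SD, n = 4) in HF, 75963 ± 16768 in N, 74198 ± 30660 in NW and 75749 ± 21588 in HFW. At these depths 1 tag equals 6.70 to 17.7 CPM (tag counts scaled to a common library size), and 1046 genes had enough tags to be tested.

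Lars2, which encodes the mitochondrial leucyl-tRNA synthetase, held 6.11% ± 2.54 (SD, n = 4) of the tags in N, 8.29% ± 0.455 in NW, 4.98% ± 1.79 in HF and 6.55% ± 1.14 in HFW. Gpx4, a glutathione peroxidase that reduces lipid peroxides, and Apoa2, an apolipoprotein of high-density lipoprotein, reached 7.47% and 7.31% of a library. Albumin (Alb) held 0.517% of the tags on average over the libraries and transthyretin (Ttr) 0.0230%. The first principal component of the 500 most variable genes held 44.5% of their variance. NW mice had a mean score of 13.2 ± 1.67 (SD, n = 4) on it, HFW mice 3.89 ± 3.0, N mice -4.23 ± 9.0 and HF mice -12.8 ± 3.31. Within each diet every WEPAK-fed mouse scored above every mouse without WEPAK. N mouse 4 scored -16.5, below every HF mouse, and N mouse 8 scored 4.90, above HFW mice 34, 36 and 38.

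**Figure D1:**
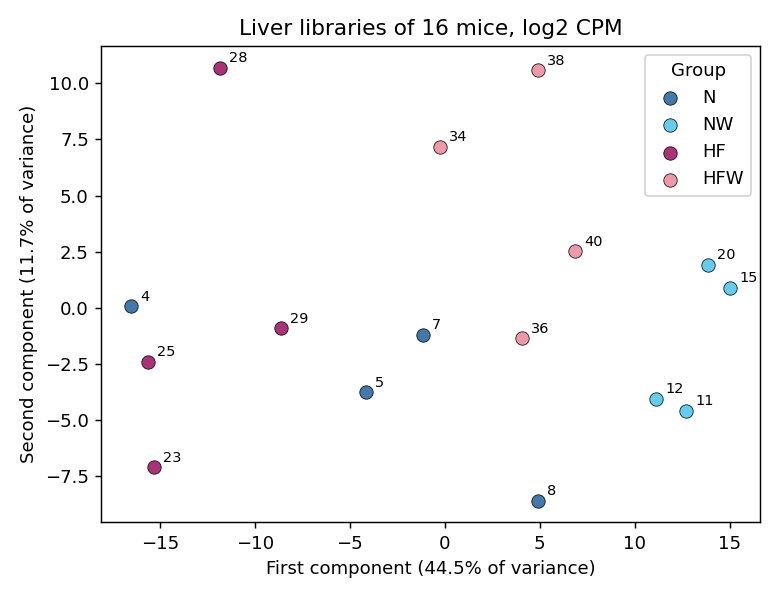
First and second principal components of log2 CPM over the 500 most variable genes, 1 point per liver library, coloured by feeding group and numbered by mouse. The 4 NW mice score 11.1 to 15.0 on the first component and the 4 HF mice -15.6 to -8.61, with N mice spread from -16.5 to 4.90.

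The first comparison asked what the high-fat diet changed without the extract. Pcsk6, a proprotein convertase, was the 1 gene that passed the test. It had 443 ± 259.6 CPM (SD, n = 4) in HF and 94.9 ± 86.2 CPM in N, a log2 fold change of 2.24 (SE 0.45) with 4 of 4 HF mice above the N mean (adjusted p = 0.0282, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Scd1, the desaturase that makes monounsaturated fatty acids, had 3569.8 ± 773 CPM in HF and 8497 ± 2189 CPM in N. Its log2 fold change of -1.25 (SE 0.30), lower in 4 of 4 HF mice, did not pass (adjusted p = 0.0925, edgeR quasi-likelihood test) and did with the DESeq2 Wald test (adjusted p = 0.0365). The other genes with the smallest p did not pass either. Their log2 fold changes were 1.14 for Mtmr4, 0.98 for Fam178a, 1.05 for Ephx1, a microsomal epoxide hydrolase, 0.91 for Slc22a18, 1.22 for St3gal5, a ganglioside synthase, -1.34 for Fbxo3, -1.75 for Acaa1b, a peroxisomal thiolase, -1.07 for Eef1b2 and -0.86 for Agxt, which detoxifies glyoxylate. The last tag of Eef1b2 also occurs in transcripts of 189 other genes. Without N mouse 4 the count was 31 genes, 17 higher and 14 lower, and these passed by edgeR: Scd1 (-1.25, adjusted p = 0.0202), Mtmr4 (1.52, adjusted p = 0.0202), Fam178a (1.36, adjusted p = 0.0149), Fbxo3 (-1.39, adjusted p = 0.0342), Eef1b2 (-1.31, adjusted p = 0.0202) and Agxt (-1.05, adjusted p = 0.0209). The count was 0 without N mouse 5, 7 or 8 or HF mouse 23 or 25, with 103 genes at an unadjusted p under 0.05 when all mice were used. Pcsk6 had 3.02 without N mouse 4 (adjusted p = 0.000307) and did not pass by edgeR without N mouse 5 (2.10, adjusted p = 0.396), without N mouse 7 (2.04, adjusted p = 0.245), without N mouse 8 (2.12, adjusted p = 0.0837), without HF mouse 23 (1.96, adjusted p = 0.119) or without HF mouse 25 (2.04, adjusted p = 0.0861).

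Of 11 measured genes of periportal hepatocytes, the cells around the portal vein, 9 had a negative log2 fold change in HF against N, with a median of -0.53. Over all genes tested 0 of them passed, and adjusted over the list alone 1 was lower, Hsd17b13 (-0.83, SE 0.27), a lipid droplet protein. The list passed as a set with camera at a preset correlation (adjusted p = 0.0239) and not with an estimated one (adjusted p = 0.817 with an estimated correlation). By camera it did not pass without N mouse 5 (median -0.35, adjusted p = 0.157), HF mouse 28 (median -0.31, adjusted p = 0.262) or HF mouse 29 (median -0.56, adjusted p = 0.0529). All 9 measured genes of gluconeogenesis, glycolysis and insulin response had negative values, with a median of -0.42, and that list did not pass (camera adjusted p = 0.0534). Among them Pck1, the enzyme that commits carbon to gluconeogenesis, had -0.85 (SE 0.33) and Fbp1, a gluconeogenic phosphatase, -0.61 (SE 0.28). Over all genes 0 of the list passed, and 0 adjusted over the list alone. Of 18 genes of fatty acid oxidation and PPARalpha targets 0 passed over all genes, and 3 were lower adjusted over the list alone: Acaa1b, Acaa2 (-0.99) and Ehhadh (-1.38). Of 10 genes of fatty acid and triglyceride synthesis 0 passed over all genes and 1, Scd1, was lower adjusted over the list alone. Fasn, fatty acid synthase, had 0.21 (SE 0.42) and Srebf1, a regulator of that pathway, -0.14 (SE 0.47). The 4 measured stellate cell and fibrosis markers all had positive values, such as Col3a1 (1.15, SE 0.69), and 0 passed over all genes or adjusted over the list alone.

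Over all 1046 genes, 103 had an unadjusted p under 0.05 in HF against N, 39 higher and 64 lower. The DESeq2 Wald test called 2 genes and limma-voom 0. The groups did not overlap for 3.06% of genes, where chance gives 2.86%.

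The second comparison asked what the extract changed on the high-fat diet. Kdelr1, a receptor that returns proteins to the endoplasmic reticulum, fell from 2445 ± 869 CPM (SD, n = 4) in HF to 584 ± 185 CPM in HFW, a log2 fold change of -2.06 (SE 0.36). Igfals, the liver-made protein that holds insulin-like growth factors in the blood, fell by 1.77 on the log2 scale (SE 0.32). Dus1l, a tRNA-modifying enzyme, rose from 173 ± 68.1 CPM to 530.0 ± 97.8 CPM, a log2 fold change of 1.63 (SE 0.31). Acaa2, the mitochondrial thiolase of fatty acid oxidation, rose by 1.49 (SE 0.33), its peroxisomal relative Acaa1a by 1.28 (SE 0.31) and Acox2, an oxidase of branched-chain fatty acids and bile acid precursors, by 1.44 (SE 0.32).

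In all, 44 genes were higher and 59 lower in HFW than in HF (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Among the other higher genes with the smallest p were Eef1b2 (1.61), Trfr2 (1.27), which senses iron-loaded transferrin, Fbxo3 (1.62), Slc25a5 (1.25), a mitochondrial ADP/ATP carrier, and Sec61a1 (1.11), part of the endoplasmic reticulum translocon. As given above, the last tag of Eef1b2 also occurs in transcripts of other genes, so its counts may stem from them. The other lower genes with the smallest p were Sephs2 (-2.01), which supplies selenium for selenoproteins, Ccdc107 (-1.96), Lactb (-2.66), Bag4 (-1.65), Pcsk6 (-2.32), Cmtm4 (-1.85), Zdhhc9 (-1.90) and Nipsnap3b (-1.68). The adjusted p of these genes lay between 0.00186 (Igfals) and 0.0109 (Sec61a1) in the edgeR quasi-likelihood test, and for each 4 of 4 HFW mice lay on the side of the fold change from the HF mean. By edgeR, Sec61a1 did not pass without HFW mouse 40 (0.97, adjusted p = 0.0548) and Slc25a5 did not without HFW mouse 40 (0.97, adjusted p = 0.0635). The count was 51 (15 higher and 36 lower) without HF mouse 23, 40 (13 higher and 27 lower) without HF mouse 25, 59 (19 higher and 40 lower) without HFW mouse 38 and 65 (24 higher and 41 lower) without HFW mouse 40. With no filter it was 106 (11 higher and 95 lower). The groups did not overlap for 15.7% of genes, where chance gives 2.86%.

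All 9 genes of gluconeogenesis, glycolysis and insulin response had positive values in HFW against HF, with a median of 0.60. The same 9 genes had negative values in HF minus N. That contrast shares the HF libraries with the opposite sign, so low HF values alone would give both patterns. Of these 9 genes 1 rose, Fbp1 (1.06, SE 0.29), and 3 rose adjusted over the list alone, with Slc2a2 (0.86) and Pck1 (0.94). By edgeR over all genes, Fbp1 did not pass without HF mouse 23 (0.97, adjusted p = 0.0684), without HFW mouse 38 (0.98, adjusted p = 0.0618) or without HFW mouse 40 (0.81, adjusted p = 0.0923), and Pck1 passed without HF mouse 29 (1.15, adjusted p = 0.0335). Of 18 genes of fatty acid oxidation and PPARalpha targets 2 rose, Acaa2 and Acaa1a, and 1 fell. Adjusted over the list alone 3 rose and 2 fell. Cyp4a14, a fatty acid hydroxylase, had -1.76 (SE 0.59) and did not pass by edgeR (adjusted p = 0.0718, lower in 4 of 4 HFW mice); it passed with the DESeq2 Wald test (adjusted p = 0.0428) and without HF mouse 28 (-2.07, adjusted p = 0.0193). Of 10 genes of fatty acid and triglyceride synthesis 0 passed over all genes and 0 adjusted over the list alone, and Scd1 had 0.70 (SE 0.29).

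Of 11 lipoprotein genes 1 fell in HFW, Lcat, the enzyme that esterifies cholesterol in plasma (-1.58, SE 0.33), and adjusted over the list alone 1 rose and 1 fell. Of 17 genes of amino acid catabolism and the urea cycle 1 rose, Cbs (1.24, SE 0.34), which makes cystathionine, and 1 fell. Adjusted over the list alone 2 rose and 2 fell. By edgeR Cbs did not pass without HF mouse 25 (1.24, adjusted p = 0.0602) or without HFW mouse 40 (1.0, adjusted p = 0.0909). Of 14 secreted hepatocyte proteins 1 rose, Gc, the vitamin D carrier (1.16, SE 0.31), with the same counts adjusted over the list alone, and it did not pass by edgeR without HF mouse 23 (1.02, adjusted p = 0.0715) or without HF mouse 25 (0.97, adjusted p = 0.0944). No list passed as a set in this comparison, the smallest camera adjusted p being 0.0694 for the gluconeogenesis list.

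The third comparison asked what the extract changed on the normal diet. Bsg, a chaperone of lactate transporters, fell from 1996 ± 1602 CPM (SD, n = 4) in N to 399 ± 127 CPM in NW, a log2 fold change of -2.28 (SE 0.37). The log2 fold change was -1.91 (SE 0.33) for Igfals, -1.97 (SE 0.37) for Kdelr1 and -1.84 (SE 0.34) for Lcat. Dus1l rose by 1.68 (SE 0.31), from 264 ± 84.1 CPM to 844 ± 137 CPM, and Cbs by 1.44 (SE 0.33). N mouse 4 had 4388 CPM of Bsg, above the 1032 to 1383 CPM of the other N mice. Without N mouse 4 the log2 fold change was -1.56 (adjusted p = 0.00403 by edgeR) for Bsg and -1.36 (adjusted p = 0.0120) for Kdelr1.

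In all, 38 genes were higher and 77 lower in NW than in N (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Among the other higher genes with the smallest p were Slc25a5 (1.32), Kdm4a (1.17), a histone demethylase, Grn (1.15), Tsku (1.31), Acaa2 (1.23), Edc4 (1.54) and Sec61a1 (1.07). The other lower genes with the smallest p were Fam134a (-1.77), Ccdc107 (-2.26), Tst (-1.89), a mitochondrial sulfurtransferase, Mrps14 (-1.59), Sephs2 (-2.0) and Paqr7 (-1.37). The adjusted p of these genes lay between 0.000951 (Igfals) and 0.0125 (Sec61a1) in the edgeR quasi-likelihood test, and for each 4 of 4 NW mice lay on the side of the fold change from the N mean. By edgeR, Acaa2 did not pass without N mouse 4 (1.03, adjusted p = 0.0611), Edc4 without N mouse 4 (1.47, adjusted p = 0.0540), Sec61a1 without N mouse 4 (0.89, adjusted p = 0.0687), Slc25a5 without NW mouse 15 (1.05, adjusted p = 0.0522) and Grn without NW mouse 15 (0.87, adjusted p = 0.0770). The count was 31 (6 higher and 25 lower) without N mouse 4, 47 (13 higher and 34 lower) without NW mouse 15 and 178 (89 higher and 89 lower) without N mouse 8. It was 38 (6 higher and 32 lower) without N mice 4 and 8 together. The balance of directions changed also with no filter, at 70 (12 higher and 58 lower), and without NW mouse 12, at 79 (39 higher and 40 lower). The groups did not overlap for 15.5% of genes, where chance gives 2.86%.

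Of 10 genes of fatty acid and triglyceride synthesis 2 fell in NW against N: Acly, which makes cytosolic acetyl-CoA (-1.70, SE 0.40), and the desaturase Fads1 (-1.27, SE 0.33). Adjusted over the list alone 1 rose and 3 fell. Fads1 did not pass by edgeR without N mouse 4 (-1.22, adjusted p = 0.0566), without N mouse 5 (-0.81, adjusted p = 0.113), without NW mouse 11 (-1.16, adjusted p = 0.0520) or without NW mouse 15 (-1.22, adjusted p = 0.0541). Srebf1 had -1.26 (SE 0.49) and did not pass (adjusted p = 0.101, edgeR quasi-likelihood test, lower in 3 of 4 NW mice). It passed with the DESeq2 Wald test (adjusted p = 0.0467) and by edgeR without NW mouse 20 (-2.11, adjusted p = 0.00143). NW mouse 20 had 1982 CPM of Srebf1 and the other NW mice 412 to 444 CPM. Of 18 genes of fatty acid oxidation and PPARalpha targets 2 rose, Acaa2 (1.23) and Acads (1.26, SE 0.34), and 1 fell, Acadvl (-1.14, SE 0.27). Acads and Acadvl are acyl-CoA dehydrogenases for short and very long chains. Adjusted over the list alone 2 rose and 2 fell. Acads did not pass by edgeR without N mouse 4 (1.23, adjusted p = 0.0583), without N mouse 5 (1.11, adjusted p = 0.0546) or without NW mouse 15 (0.98, adjusted p = 0.0993), nor Acaa2 without N mouse 4 (1.03, adjusted p = 0.0611).

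Of 9 genes of gluconeogenesis, glycolysis and insulin response 0 passed over all genes in NW against N and 5 rose adjusted over the list alone, Pgk1 (1.08), Slc2a2 (0.86) and Pck1 (0.89) among them. Over all genes Pck1 passed by edgeR without N mouse 8 (1.32, adjusted p = 0.00617). Of 11 lipoprotein genes 2 fell, Lcat and Apoc1 (-0.94, SE 0.24), an inhibitor of lipoprotein uptake, with the same counts adjusted over the list alone. Apoc1 did not pass by edgeR without N mouse 4 (-0.75, adjusted p = 0.0769) or without NW mouse 15 (-0.89, adjusted p = 0.0544). Of 3 measured clock genes 1 fell, Nr1d1, a repressor of the clock (-1.37, SE 0.34), and 2 rose and 1 fell adjusted over the list alone. No list passed as a set, the smallest camera adjusted p being 0.314.

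The mean of both extract contrasts uses all 16 mice. Of 9 measured genes of gluconeogenesis, glycolysis and insulin response 5 rose with WEPAK and 0 fell, with the same counts adjusted over the list alone. Pck1 had a log2 fold change of 0.92 (SE 0.23), Fbp1 of 0.92 (SE 0.20) and the glucose transporter Slc2a2 of 0.86 (SE 0.21). The list as a set did not pass (camera adjusted p = 0.155).

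Over all genes, 159 were higher and 168 lower with WEPAK (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Among the higher genes with the smallest p were Dus1l (1.65), Acaa2 (1.36), Eef1b2 (1.32), Trfr2 (1.09), Acox2 (1.38), Slc25a5 (1.29), Cbs (1.34), Fbxo3 (1.32) and Sec61a1 (1.09). The counts of Eef1b2 may stem from other genes that share its last tag. The lower genes with the smallest p were Igfals (-1.84), Kdelr1 (-2.02), Ccdc107 (-2.11), Bsg (-1.92), Sephs2 (-2.0), Lcat (-1.71), Mrps14 (-1.46), Tst (-1.70), Cmtm4 (-1.87) and Fam134a (-1.45). The adjusted p of these genes lay between 3.45e-06 (Igfals) and 0.000154 (Sec61a1) in the edgeR quasi-likelihood test, and for each 8 of 8 WEPAK-fed mice lay on the side of the fold change from the mean of the other group on their diet. With no filter the count was 254 (65 higher and 189 lower).

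**Figure D2:**
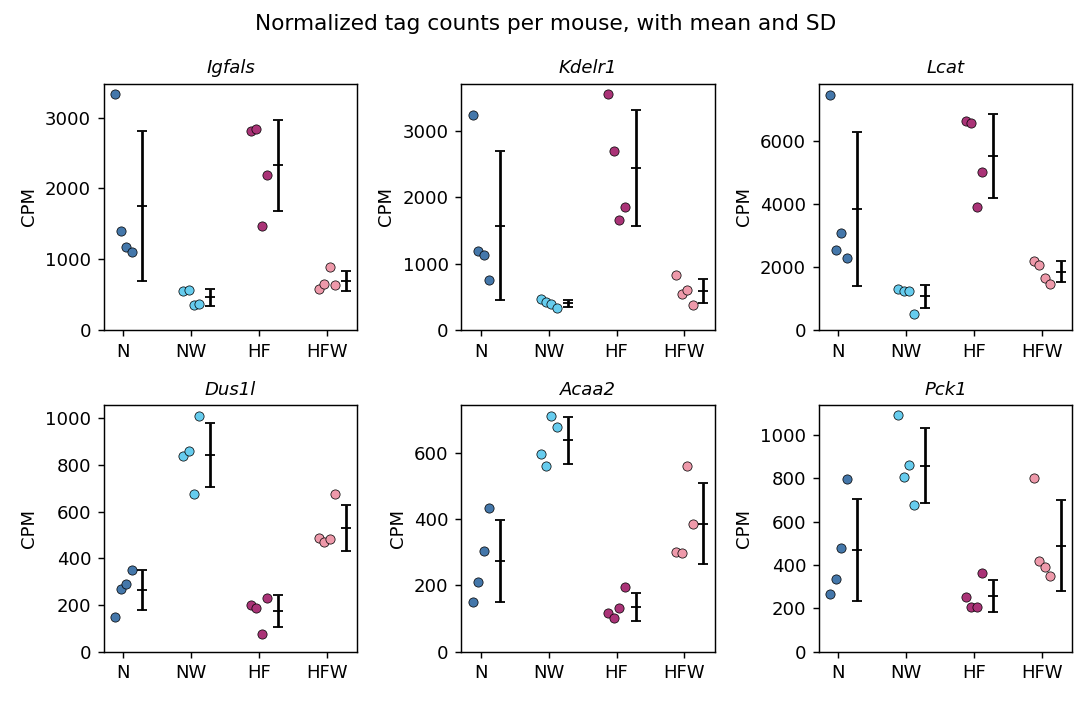
Normalized tag counts (CPM, linear axis from 0) of 6 genes in each of the 16 livers, by feeding group; points are mice, and the mark beside them is the mean with 1 SD (n = 4). Igfals, Kdelr1 and Lcat have lower means and Dus1l, Acaa2 and Pck1 higher means with WEPAK on either diet, and N mouse 4 has 3332 CPM of Igfals and 7482 CPM of Lcat.

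Genes of lipid metabolism moved in both directions in the mean effect. Of 10 synthesis genes 2 rose, Thrsp (1.46, SE 0.37), a lipogenic regulator, and Dgat2 (0.67, SE 0.21), the last enzyme of triglyceride synthesis, and 2 fell, Acly (-1.22, SE 0.27) and Fads1 (-0.96, SE 0.23), with the same counts adjusted over the list alone. Of 18 oxidation genes and PPARalpha targets 3 rose, Acaa2, Acads (1.12) and Acaa1a (1.02), and 3 fell, Acadvl (-0.88) among them, with 3 and 4 adjusted over the list alone. Of 11 lipoprotein genes 2 rose, Apoc2 (1.16, SE 0.39) and Pltp (0.56, SE 0.22), and 2 fell, Lcat and Apoc1 (-0.75), with the same counts adjusted over the list alone. By edgeR, Apoc2 did not pass without NW mouse 15 (0.94, adjusted p = 0.0891), without HF mouse 25 (1.05, adjusted p = 0.0592), without HF mouse 29 (1.07, adjusted p = 0.0511) or without HFW mouse 38 (1.06, adjusted p = 0.0553). Pltp did not pass without N mouse 5 (0.50, adjusted p = 0.0876), without N mouse 8 (0.54, adjusted p = 0.0572), without NW mouse 12 (0.57, adjusted p = 0.0593), without NW mouse 15 (0.45, adjusted p = 0.134), without HF mouse 23 (0.46, adjusted p = 0.109), without HF mouse 25 (0.57, adjusted p = 0.0649), without HF mouse 29 (0.55, adjusted p = 0.0663) or without HFW mouse 38 (0.38, adjusted p = 0.189), with DESeq2 size factors (0.54, adjusted p = 0.0529) or with the DESeq2 Wald test (0.54, adjusted p = 0.0575). Scd1 (0.41, SE 0.21), Fasn (0.21, SE 0.30), Srebf1 (-0.71, SE 0.34) and Cyp4a14 (-1.07, SE 0.41) did not pass. By edgeR Srebf1 passed without NW mouse 20 (-1.13, adjusted p = 0.000931), and Cyp4a14 without NW mouse 20 (-0.86, adjusted p = 0.0139) or without HF mouse 28 (-1.19, adjusted p = 0.0165) and with the DESeq2 Wald test (adjusted p = 0.0449).

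Of 17 genes of amino acid catabolism and the urea cycle 4 rose, Cbs, Tdo2 (1.10) and Agxt (0.64) among them, and 3 fell, Arg1 (-0.65) among them, with the same counts adjusted over the list alone. Arg1 did not pass by edgeR without N mouse 5 (-0.55, adjusted p = 0.0519) or without HF mouse 23 (-0.53, adjusted p = 0.0605). Of 10 antioxidant and glutathione genes 3 fell: Sod2 (-1.97, SE 0.44), the mitochondrial superoxide dismutase, whose last tag also occurs in 1 other gene, Gclc (-0.61) and Ephx1 (-1.04). In that list 1 gene rose, Sod1 (0.74, SE 0.25), which did not pass by edgeR without N mouse 4 (0.63, adjusted p = 0.0546), without NW mouse 11 (0.68, adjusted p = 0.0547), without HF mouse 29 (0.66, adjusted p = 0.0511), without HFW mouse 38 (0.69, adjusted p = 0.0512) or without HFW mouse 40 (0.59, adjusted p = 0.0845). There 2 rose and 3 fell adjusted over the list alone. Of 7 drug-metabolizing cytochromes P450 2 rose, Cyp2d10 (0.95) and Cyp2d22 (0.62), and 1 fell, Cyp2c29 (-1.34), with the same counts adjusted over the list alone. Of 14 secreted hepatocyte proteins 3 rose, Gc (0.91), Ambp (0.73) and Ttr (0.85), and 0 fell, with the same counts adjusted over the list alone. Of 3 measured clock genes 2 rose, Tef (0.56) among them, and 1 fell, Nr1d1 (-0.95), with the same counts adjusted over the list alone. Tef did not pass by edgeR without N mouse 4 (0.46, adjusted p = 0.0592) or without NW mouse 11 (0.51, adjusted p = 0.0559). Markers of macrophages (2 measured) and of stellate cells (4 measured) gave 0 calls by edgeR over all genes and adjusted over the list alone. No list passed as a set with camera for the mean effect.

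Other markers of these cells lay below the filter. Vsig4, a complement receptor of Kupffer cells, the macrophages of the liver, had 26 tags in N and 3 in NW, 51 in HF and 11 in HFW, summed over 4 mice each. Tag sums here are not scaled for depth, which was greatest in HF. In CPM the group means of Vsig4 were 79.0 ± 39.4 (SD, n = 4) in N and 12.1 ± 24.3 in NW. They were 109.7 ± 59.0 in HF and 34.5 ± 35.4 in HFW. In a fit of 10171 genes with no filter it fell in the mean effect, with a log2 fold change of -2.22 (SE 0.47, adjusted p = 0.000336, edgeR quasi-likelihood test), with 4 of 4 NW mice below the N mean and 4 of 4 HFW mice below the HF mean. The p values of the markers in this fit were those of a normal distribution at the log2 fold change over its SE. A marker's own spread between mice thus hardly entered them, and the adjusted p of Vsig4 can be too small. On the diets taken singly Vsig4 passed in NW minus N (adjusted p = 0.0431) and not in HFW minus HF (-1.63, SE 0.56, adjusted p = 0.180), both by edgeR. The interaction called 0 genes by edgeR with no filter (304 at an unadjusted p under 0.05), so a difference between the diets was not shown for it. Mice were left out only for the mean effect. There it passed with each of the 16 mice left out, and the log2 fold change nearest to 0 was -1.88 (adjusted p = 0.00822 by edgeR) without NW mouse 12. All NW tags of Vsig4 were in NW mouse 20, so the fitted value without that mouse is no bound and is not given. Tyrobp had 14 tags in N and 5 in NW, 32 in HF and 13 in HFW, and Csf1r 40 tags in N and 29 in NW, 36 in HF and 31 in HFW, and neither passed in that fit (-1.05, adjusted p = 0.398, and -0.087, adjusted p = 1.000, edgeR quasi-likelihood test). In CPM Tyrobp had group means of 70.5 in HF and 43.0 in HFW. Csf1r had 77.9 in HF and 89.6 in HFW, a log2 fold change of 0.25 (SE 0.47) that did not pass. Gpnmb, another macrophage marker, went the other way from Vsig4 on the high-fat diet, with 4 tags in HF and 16 in HFW. It did not pass (2.33, SE 0.84, unadjusted p = 0.00575, adjusted p = 0.257, edgeR quasi-likelihood test), and it had 0 tags in N and 0 in NW. In the mean effect, of 20 macrophage markers with tags below the filter 13 had negative values and 1 passed, and of 13 stellate cell markers 5 and 0. These counts of signs say little. Some markers had an SE far above their value on either side, such as Itgax (-0.66, SE 1498, 1 tag) and Fcer1g (0.83, SE 2052, 1 tag). Over all genes of that fit the median was -0.0148, so negative values were common there.

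The effects of the extract on the normal and the high-fat diet share no library. Genes called on both diets were 15 higher and 33 lower ones, where independent calls would share 1.60 and 4.34, and 0 genes were called in opposite directions. Of the 115 genes called on the normal diet, 111 had the same sign on the high-fat diet, and of the 103 called on the high-fat diet 102 did on the normal diet. Across 1046 genes, which are not independent replicates, the log2 fold changes correlated with Pearson's r = 0.756 and Spearman's rho = 0.726. Mice of 1 group also differed along this profile. The deviation of N mouse 4 from the N mean correlated with HFW minus HF at r = -0.589, and that of N mouse 8 at 0.451. The other N and NW mice gave -0.192 to 0.258. An axis between mice can therefore add to the overlap and to r, and how much was not tested.

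**Figure D3:**
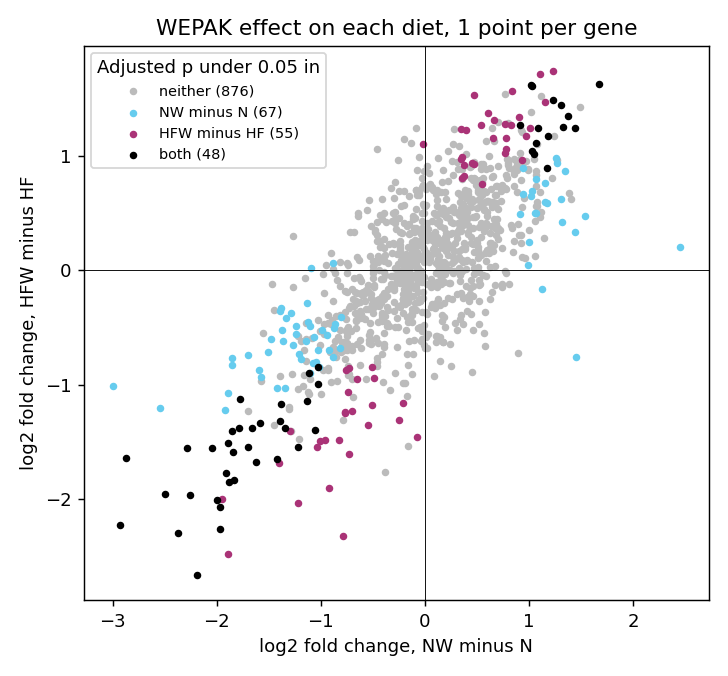
Log2 fold change of each of 1046 genes with WEPAK on the normal diet (horizontal axis, NW minus N) and on the high-fat diet (vertical axis, HFW minus HF), coloured by the comparison in which the gene passed. The genes that passed in both were lower in both (33) or higher in both (15).

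The interaction asked whether the extract acted differently on the normal and the high-fat diet. The genes with the smallest p did not pass. Their log2 differences were -2.21 (SE 0.61) for St3gal5, -1.28 for Pqlc1, -1.62 for Strbp, -1.34 for Ralgapb and -2.25 for Zbtb16, and 0.94 for Anapc5, 1.04 for Dsp, a desmosome protein, 1.12 for Ldha, which makes lactate, 1.56 for Pvrl3 and 1.13 for Dpp3. Pck1 differed by 0.052 (SE 0.44) and Scd1 by 0.58 (SE 0.41). The count was 0 of 1046 genes (smallest adjusted p = 0.998, edgeR quasi-likelihood test), with 26 genes at an unadjusted p under 0.05, and the DESeq2 Wald test called 0 and limma-voom 0. The median standard error was 0.50 on the log2 scale, so small differences between diets could go undetected. Whether depth, the number of mice or their spread set that limit was not tested. No list passed, the smallest camera adjusted p being 0.122 for cytochromes P450.

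The last pairwise comparison asked what the high-fat diet changed among extract-fed mice. Ephx1 had 172 ± 28.1 CPM (SD, n = 4) in HFW and 40.8 ± 31.0 CPM in NW, a log2 fold change of 1.94 (SE 0.48) that did not pass (adjusted p = 0.175, edgeR quasi-likelihood test, higher in 4 of 4 HFW mice). The next genes did not pass either, with 1.08 for Anapc5, 1.16 for Ptprf, 1.07 for Paqr7, 1.58 for Entpd5, -1.24 for Ralgapb, -0.89 for Ak3, -1.16 for Cps1, the first enzyme of the urea cycle, -1.09 for Mttp, which loads lipid onto lipoproteins, and -0.88 for Pqlc1. The count was 0 of 1046 genes with the edgeR quasi-likelihood test, with 126 genes at an unadjusted p under 0.05, and the DESeq2 Wald test called 0 and limma-voom 0. A fit of these 8 mice alone called 3 genes, 3 of them higher. Without NW mouse 20 the count was 3, among them Srebf1 (1.86, adjusted p = 0.0197 by edgeR) and Cyp4a14 (-1.83, adjusted p = 0.0243).

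Periportal hepatocyte genes had negative values for 10 of 11 members in HFW against NW, with a median of -0.43. The set passed with camera (adjusted p = 0.00998) and not with an estimated correlation (adjusted p = 0.817 with an estimated correlation). Over all genes 0 members passed and adjusted over the list alone 1 was lower, Cps1. All 7 cytochromes P450 had negative values, with a median of -0.44 (camera adjusted p = 0.0534). The groups did not overlap for 8.80% of genes, where chance gives 2.86%.

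The diet effects without and with the extract share no library. Their log2 fold changes correlated across genes, which are not independent replicates, with r = 0.499 and rho = 0.484, and 66.3% of genes had the same sign.

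The diet effect and the extract's effect on the high-fat diet share the HF libraries with opposite signs, which alone gives opposite values. Pcsk6, the 1 gene called for the diet, had -2.32 with the extract, so the called gene had the opposite sign. Over all genes 74.4% had opposite signs in mean log2 CPM, against 59.3% when HFW libraries without an extract effect were simulated. The correlation across genes, which are not independent replicates, was -0.669 (simulated -0.281). The simulation drew each gene independently, without shifts that many genes of a library share. It therefore cannot tell how much of either gap such shifts would give. The simulation also took the fitted N and HF means as true, so chance differences between these groups entered it as a diet effect. That weakens the simulated opposition, so both gaps can look larger than they are, by an amount that was not measured. With the HF mice split 2 and 2, so that each effect used different HF mice, the mean r over 6 splits was -0.403, from -0.559 to -0.115.

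Of 14 genes of lipid and glucose metabolism and inflammation chosen in advance, 5 were deep enough to test. Over the 16 libraries together Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had 82 tags, Cd36 33, Saa1 28, Cidec 15 and Pparg 13. Sqle, Cidea and Fgf21 had 0 tags. So did Rpsa and Rplp1, which encode ribosomal proteins, so a count of 0 can also mean that no tag was assigned to the gene, and it sets no limit on expression.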

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

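The tests of library depth, of NlaIII sites, of an axis between mice of a group and of other splits of the mice were chosen after the results were seen.

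In 26 of 392 sets of 4 values, a mouse lay far from the other 3 by Dixon's criterion, where chance gives about 1 in 20, or 20. N mouse 4 had 223 CPM of Pcsk6, 3332 of Igfals, 4388 of Bsg, 20097 of Fam134a and 7482 of Lcat, each above the other N mice. N mouse 7 had 596 CPM of Dsp. NW mouse 12 had a total of 120229 tags, 5331 genes detected, 357 CPM of Pqlc1 and 901 CPM of Slc10a1. NW mouse 20 had 7.61% of its tags in Lars2, 1982 CPM of Srebf1, 521 of Lcat, 191 of Strbp and 330.3 of Atp5j2, and NW mouse 11 had 239 of Edc4. HF mouse 23 had 137 CPM of Acaa1b and 547 of Apof, and HF mouse 29 had 1153 of Ptprf and 14953 of Dgat2. HFW mouse 38 had 149 CPM of Pcsk6, HFW mouse 40 had 272 of Eef1b2, 676 of Dus1l and 329 of Acly, and HFW mouse 34 had 801 of Pck1 and 939.8 of Herpud1.

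The mean WEPAK effect over both diets covered 327 genes. GC content of the tag (r = 0.0125 with the fold change across genes) and of the transcript (r = 0.0480) were argued against as the whole cause. So was the number of NlaIII sites, by the 313 calls with that trend removed, though its r of 0.156 on the log2 scale was larger. So was library depth: with all libraries thinned to the smallest total 282 genes were called, and 256 to 296 in 10 random draws. An axis of variation that also parts mice of a group cannot be told apart from the extract. The first such axis correlated with the effect at 0.442 and the second at 0.546. With HF minus N they correlated at 0.535 and 0.255. Recomputed with 1 mouse left out, the first axis gave 0.148 without N mouse 4 and 0.0765 without N mouse 8. Without any other mouse it gave 0.371 to 0.595. Only the first axis was recorded, and leaving out a mouse can change which axis is first. The low values therefore do not show that the match rests on 1 mouse. An effect of the extract stays open beside such an axis, as does a batch that followed the groups.

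Other ways of dividing the same mice tested the counts. For HFW minus HF 1 of 35 splits, the real one, gave as many as 103 genes and the highest other 14. For NW minus N 1 of 35, the real one, gave as many as 115 and the highest other 11. With 35 splits no fewer than 1 can reach the real count, and several contrasts were tested this way. The splits therefore argue against chance in these contrasts but do not exclude it. For the mean WEPAK effect 1 of 100 splits, the real one, gave as many as 327 and the highest other 78. Those 100 were only a part of the possible splits, so chance is argued against there too, not excluded. Chance is not argued against for HF minus N, where 3 of 35 splits gave at least the real 1 gene. There N mouse 4 with HF mice 23, 25 and 28 against the rest gave 56. For HFW minus NW and the interaction the splits test nothing, because the real counts were 0 and 0 and so 35 of 35 and 100 of 100 splits reach them whatever the data. The highest other counts there were 1 and 55, the latter for N mice 7 and 8, the NW mice, HF mouse 29 and HFW mouse 36 against the rest. Splits with 56 and 55 calls point to a structure of the samples. The mice put together in the split with 56 calls, N mouse 4 and HF mice 23, 25 and 28, scored -16.5 to -11.8 on the first component, below all others. The cause of that structure was not tested.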

How the results depend on the processing

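Chosen after seeing the data were thinning, the trend removals, leaving out the 10 most abundant genes, leaving out N mice 4 and 8, the fit of cell markers below the filter, other prior counts, and the abundant genes for the WEPAK agreement. The count for HF minus N was 2 with the DESeq2 Wald test, 0 with limma-voom, 0 with only the groups compared and 0 with thinned libraries, and 0 to 31 with 1 mouse left out. HFW minus HF gave 75 to 119 in the settings run with all mice and 40 to 150 with 1 left out. NW minus N gave 70 with no filter, 38 without N mice 4 and 8, and 31 to 178 with 1 mouse left out. HFW minus NW gave 3 with only the groups compared and 0 to 3 with 1 mouse left out. The mean WEPAK effect gave 254 to 338 over the other settings and 263 to 386 with 1 mouse left out. The interaction gave 0 by edgeR, the Wald test, limma-voom and the other settings run, with 26 genes at an unadjusted p under 0.05. With no filter the higher and lower genes were 11 and 95 in HFW minus HF, 12 and 58 in NW minus N, and 65 and 189 in the mean WEPAK effect, against 44 and 59, 38 and 77, and 159 and 168 with it, so the balance of directions depends on the filter. Macrophage markers called in the mean WEPAK effect were 0 with the filter and 1 with no filter, and stellate cell markers 0 and 0. As given above, the p values of these markers with no filter hardly took in their spread between mice. List calls were 0 with an estimated correlation, 0 with fry, and 1 to 8 with 1 mouse left out. The correlation of diet effects was 0.608 and that of WEPAK effects 0.827 over genes above the median abundance. Except for fewer mice or tags, the cause was not tested. With prior counts of 0.5 and 5 in log2 CPM, in place of 2, 2 and 2 lists were called, 73.9% and 74.5% of genes had opposite signs in HF minus N and HFW minus HF, with r of -0.659 and -0.678, and the first component held 41.2% and 47.7% of the variance.

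Of 130 named calls, 39 were lost with at least 1 mouse left out, 3 with DESeq2 size factors, 3 with the Wald test, and 0 reversed. Signs turned for genes that had not passed. With 1 mouse left out, Fasn ran from -0.19 to 0.80 in HF minus N, -0.19 to 0.71 in NW minus N and -0.42 to 0.55 in the interaction. Srebf1 ran from -0.30 to 0.26 in HF minus N and -0.41 to 0.034 in HFW minus HF, Cyp4a14 from -0.30 to 0.29 in HF minus N and -0.58 to 0.057 in NW minus N, Scd1 from -0.054 to 0.36 in NW minus N, and Pck1 from -0.39 to 0.25 in the interaction, where it was -0.00056 with DESeq2 size factors. The cause was not tested. A level of 3 tags in a library was 20.1 to 53.0 CPM. The filter also left out genes above that level, such as Csf1r, with group means of 77.9 to 129.9 CPM.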

Other observations

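The tests of tag position and of shared tags were chosen after the result was seen.

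In the mean WEPAK effect, Fitm1, which helps to form lipid droplets, fell (-1.23, SE 0.24), the 1 call among 4 measured genes of lipid droplets and fatty acid uptake, with the same counts adjusted over the list alone. Of 6 nuclear genes of oxidative phosphorylation 2 fell, Ndufb9 (-0.69) and Atp5j2 (-0.73), with the same counts adjusted over the list alone. Of 7 genes of endoplasmic reticulum stress 1 rose, Herpud1 (0.86, SE 0.23), with the same counts adjusted over the list alone.

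Lars2 held 3.26% to 9.70% of the tags of a library. Tags of the mitochondrial 16S ribosomal RNA, counted as Lars2, cannot be told apart from tags of Lars2 itself. Of the GENCODE transcripts, 0 of 107 NlaIII tags of Lars2 transcripts occur in that RNA, and the longest exact match was 12 nucleotides, but the table counted tags on RefSeq transcripts of a release that is not given and whose sequence was not at hand. No biological explanation was tested.

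Of 167 members of the lists of secreted hepatocyte proteins, cytosolic ribosome and oxidative phosphorylation, 144 had fewer than 160 tags over all libraries. A short stretch between the last NlaIII site and the transcript end could lower the count and cannot be told apart from low abundance. Spearman's rho of tags with that distance was 0.126 over 19 tested members with an unshared tag (0.164 over 104 members, computed first). Over all 17269 genes with an unshared tag, of which these 104 are a small part, rho was 0.0292. Only genes past the filter are among the 19, so their rho says little about the low members. Tags shared with other genes cannot be told apart either: 33.8% of the 130 low members with a known tag shared it, against 21.7% of the 23 others. No biological explanation was tested.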
